A study of Mus musculus with 18 samples.

How the data were processed

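RNA sequencing of sorted mouse bone marrow B cells was analysed from 18 libraries, each from an animal with its own number in the labels. The animals were C57BL/6 mice aged 12 to 16 months. Per the labels' protocols, marrow was flushed from femurs, cells that were CD45.2+ B220+ Mac1- were sorted by flow cytometry, and polyA RNA libraries were made with an Illumina TruSeq kit. Both genotypes carried a Vav-Cre transgene, which is active in blood-forming cells. The del/del libraries carried 2 deleted Smchd1 alleles, and the heterozygous (del/+) libraries carried 1 deleted and 1 intact allele, so the heterozygous libraries were the only controls. There were 5 heterozygous and 5 del/del female libraries and 4 heterozygous and 4 del/del male libraries. Replicate numbers were given in accession order and name a library without pairing it. The labels state no pairs, but deviations from the genotype mean correlated by more than 0.1 in all 4 male and 3 of 5 female pairs of a del/del animal and the heterozygous animal of the nearest number. The remaining female pairs were at 0.0984 and -0.042. Values from a fit with these pairs are given beside male results whose call they end. For females the number of calls with these pairs is given.

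The authors deposited raw read counts per gene, 1 column per library, in a table for each sex. Per the submitters' processing notes, bcl2fastq, FastQC, Trim Galore and TopHat were used, the genome builds named were mm10 and GRCm38, and edgeR 3.32.1 was used. The counting program, the annotation release and the strand setting were not given in the sources used here, so reads of overlapping or antisense genes could not be told apart. The count tables held 25965 rows, of which 56 had no gene identifier and took at most 0.0846% of any library's counts. These rows carried a gene symbol and stayed in the fits. Of the row identifiers, 24990 were found in GENCODE M21. The 13 mitochondrial rows held 0 counts, and 124 rows shared a symbol with another row and were kept apart by position. There were 2 columns of group means in each table, which were not used here. The authors also deposited log2 fold changes between genotypes and p-values with adjusted p-values per gene, per the file headers, in the layout of an edgeR quasi-likelihood test. Their filter was not given in the sources used here. These values are quoted only beside the authors' deposited table.

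Counts were tested as deposited in R 4.3.3 with edgeR 4.0.16. For each sex, genes were kept with filterByExpr at its default settings (minimum count 10, minimum total count 15), scaled with TMM factors and tested with the quasi-likelihood test of del/del against heterozygous libraries, so a positive log2 fold change means higher in del/del. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. The sexes were fitted apart because they were deposited apart, and the interaction of sex and genotype was fitted over all 18 libraries. CPM are the usual depth-scaled counts, with TMM factors applied, given as mean ± SD over libraries. For a gene with 0 reads in a group, the fold was computed against a floor of 3 reads over the whole group, which covers counting error only. The X-linked share of calls was tested with Fisher's exact test, two-sided, against autosomal genes. The shift of X-linked genes other than Xist was tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with a correlation estimated from the libraries and with fry. The X-linked share of counts was compared with an exact permutation test, two-sided.

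Before the data were examined, 23 gene lists were fixed: X-linked genes that escape X inactivation, X-linked immune genes, clustered protocadherins, imprinted genes, the Snrpn cluster, Hox genes, pro-B and pre-B cell, mature B cell, B identity, plasma cell, age-associated B cell, germinal centre and activation, interferon, proliferation, p53 target, silencing factor, myeloid, T and NK cell, erythroid, plasmacytoid dendritic cell, stem and progenitor, stroma and megakaryocyte, and Y-linked genes. The Snrpn cluster list was written from earlier work on Smchd1. A list was tested with camera if at least 3 members passed the filter, and adjusted over the lists of that comparison. The level of a list in a library was the mean log2 CPM of its tested members. Ighm, Igkc and Ighd had no row under that name or identifier and were not analysed here. The main tests, the alternatives planned and the rule for named genes were also fixed before the data were examined. The rule named Smchd1 and Xist, up to 8 higher and 8 lower called genes of the smallest p with a mean log2 CPM of at least 1 and a regular symbol, up to 4 members of each list with the smallest p, up to 10 interaction calls and up to 10 genes called in both sexes. Genes named outside the rule are said to have been chosen after their values were seen.

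Library totals ranged from 9788112 to 29405395 counts, so that 1 count was worth between 0.034 and 0.102 CPM. Male heterozygous libraries were shallower (mean 14994939 ± 4514386 counts, SD, n = 4) than male del/del libraries (mean 21496932 ± 1312109 counts, SD, n = 4). No pair of libraries of a group agreed within sampling noise; the smallest chi-square per degree of freedom was 6.27.

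The fits were tested on simulated counts drawn from the means, dispersions and library sizes of each comparison, with a seeded set of changed genes. In the female simulation of 13352 genes, 44.9% of genes changed 1.5-fold, 74.0% of those changed 2-fold and 97.8% of those changed 4-fold were recovered, with 6 false calls. In the male simulation of 13305 genes these shares were 58.0%, 84.0% and 93.9%, with 9 false calls. In the interaction simulation of 13893 genes they were 26.5%, 63.3% and 79.6%, with 15 false calls among 13696 unchanged genes. The changed genes were drawn at random from tested autosomal genes, and libraries were simulated independently. These shares and false calls therefore do not describe genes with few counts or libraries that share a structure.

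Alternatives fixed at the start were RLE factors, TMM factors from autosomal genes, no filter and a stricter filter on low counts (at least 1 CPM in all libraries of a group), voom with sample weights, DESeq2 1.42.0, all 18 libraries in one fit, an adjusted p under 0.01, removal of V, D and J segments, a surrogate variable from sva 3.50.0, an estimated correlation, fry, and each library left out in turn. Alternatives added after seeing the data were thinning to the smallest library, covariates for Malat1, for a plasmacytoid dendritic cell score and for an erythroid score, the escape list without Xist, and pairs of animals with the nearest numbers.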

Results

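The data were gene counts of CD45.2+ B220+ Mac1- cells, a sort for B cells, from the bone marrow of 12 to 16 month old mice in which the chromatin silencing protein SMCHD1 was deleted in blood-forming cells by Vav-Cre. There were 5 heterozygous and 5 del/del female libraries and 4 heterozygous and 4 del/del male libraries. Total counts were 28789372, 11650350, 29405395, 18244118 and 23182007 in female heterozygous libraries and 19133963, 24188959, 25250778, 22160119 and 20607932 in female del/del libraries. They were 9788112, 19958091, 17280733 and 12952818 in male heterozygous libraries and 21237332, 22387081, 22614546 and 19748770 in male del/del libraries. The comparisons asked which genes differ when the remaining Smchd1 allele is lost, in each sex, and whether X-linked genes take part, since SMCHD1 is known for its role in X inactivation.

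Smchd1 transcripts (ENSMUSG00000024054, mm10 chromosome 17, 71344489 to 71475343) were lower in del/del libraries of both sexes. In females the level was 250 ± 16.2 CPM in heterozygous and 142 ± 18.4 CPM in del/del libraries (SD, n = 5 each), a log2 fold change of -0.82 (SE 0.09, edgeR quasi-likelihood adjusted p = 0.00119). In males it was 294 ± 21.4 and 176 ± 15.3 CPM (SD, n = 4 each), a log2 fold change of -0.74 (SE 0.08, adjusted p = 0.00888). No del/del library reached the level of any heterozygous library of its sex. The counts cover the whole gene, and the labels do not say which part was deleted. The male call was lost without heterozygous library 1 (adjusted p = 0.0525), del/del library 1 (0.0540) or del/del library 3 (0.0538), and with the plasmacytoid dendritic cell score of each library as a covariate (log2 -0.62, SE 0.10, adjusted p = 0.162). The log2 fold change was between -0.80 and -0.69 over the 8 fits that left out a library.

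In the female comparison, most genes called higher in del/del libraries had low levels in heterozygous libraries. Prox1, a homeobox transcription factor of lymphatic endothelium (ENSMUSG00000010175, chromosome 1, 190118038 to 190170680), rose from 2.87 ± 0.704 to 43.1 ± 5.34 CPM, a log2 fold change of 3.90 (SE 0.17, adjusted p = 1.38e-07). Isl1, a LIM homeodomain factor of motor neurons (chromosome 13), rose from 0.938 ± 0.470 to 13.97 ± 5.31 CPM. Tjp1, which encodes the tight junction protein ZO-1, rose from 1.13 ± 0.701 to 14.4 ± 4.85 CPM (log2 3.73, SE 0.37, adjusted p = 0.000358). The cell adhesion genes Ncam1 (log2 2.32, SE 0.24, adjusted p = 0.000631) and Fat3 (log2 3.70, SE 0.46, adjusted p = 0.00248) rose as well (n = 5 and 5 throughout).

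Of 13501 genes tested in females, 34 were called, 33 higher and 1, Smchd1, lower. The 33 higher genes had a median log2 fold change of 3.05, and 21 of them had a mean under 1 CPM in heterozygous libraries. At an unadjusted p under 0.05 there were 580 genes, 421 higher and 159 lower. The count was 56 with voom, 92 with DESeq2, 58 with all 18 libraries in one fit and 23, all among the 34, with pairs of nearest animal numbers. It was 13 with the erythroid score of each library as a covariate. Under that covariate the calls of Fat3 (adjusted p = 0.192), Ndn (0.0529), Dmrt2 (0.300), 1810030O07Rik (0.147) and Ifi27l2a (0.155) were lost. Their log2 fold changes there were 3.17 (SE 0.66), 4.41 (SE 0.73), 2.02 (SE 0.45), 0.55 (SE 0.11) and 0.73 (SE 0.15), and over the 22 lost calls the median ratio of the log2 fold change to that without the covariate was 0.927 and that of the SE 1.29. Ndn (adjusted p = 0.103) and Ifi27l2a (0.782) were not called with all 18 libraries either. The authors' deposited table for females held 35 genes at an adjusted p under 0.05, which included all 34.

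Some imprinted and clustered genes were among the female calls. Of 40 tested imprinted genes, 4 rose and 36 did not pass the test; adjusted over the list alone, 6 were higher and 1 lower. Peg3, a paternally expressed zinc finger gene (chromosome 7), rose from 0.551 ± 0.405 to 17.8 ± 3.22 CPM (log2 5.03, SE 0.38, adjusted p = 2.26e-05). The other 3, Peg12, Mkrn3 and Ndn, are paternally expressed genes of the Snrpn cluster on chromosome 7, the region of Prader-Willi syndrome. Their log2 fold changes were 2.24 (SE 0.16, adjusted p = 1.62e-05), 2.52 (SE 0.31, adjusted p = 0.00200) and 4.12 (SE 0.55, adjusted p = 0.00357). Of the 5 tested members of the Snrpn cluster, 3 rose, and adjusted over the list alone also 3; the list was written from earlier work on Smchd1. The camera test placed the Snrpn cluster (4 of 5 positive, median 2.24, adjusted p = 9.36e-29) and the imprinted list (adjusted p = 1.40e-08) above other genes, but the latter had 21 of 40 members positive, a median of 0.047 and a mean of 0.42. With an estimated correlation the values were adjusted p = 0.000223 and adjusted p = 0.00497.

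Of 7 tested rows of the protocadherin clusters, which encode neuronal cell surface proteins, 1 rose in females and 6 did not pass the test; adjusted over the list alone, 3 were higher. The row that rose, Pcdhac1 (ENSMUSG00000007440, chromosome 18, 36930285 to 37187657), spans the alpha cluster, so its reads cannot be assigned to a single alpha gene. It went from 0.560 ± 0.277 to 9.66 ± 1.25 CPM (log2 4.04, SE 0.27, adjusted p = 1.39e-05). Pcdhb5 had a log2 fold change of 2.63 (SE 0.51) that did not pass the test (adjusted p = 0.0685) but was called with voom (adjusted p = 0.0321), DESeq2 (0.000923) and all 18 libraries in one fit (0.0131). The list median was 0.93, with camera adjusted p = 2.52e-16 and adjusted p = 0.000367 with an estimated correlation.

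**Figure D1:**
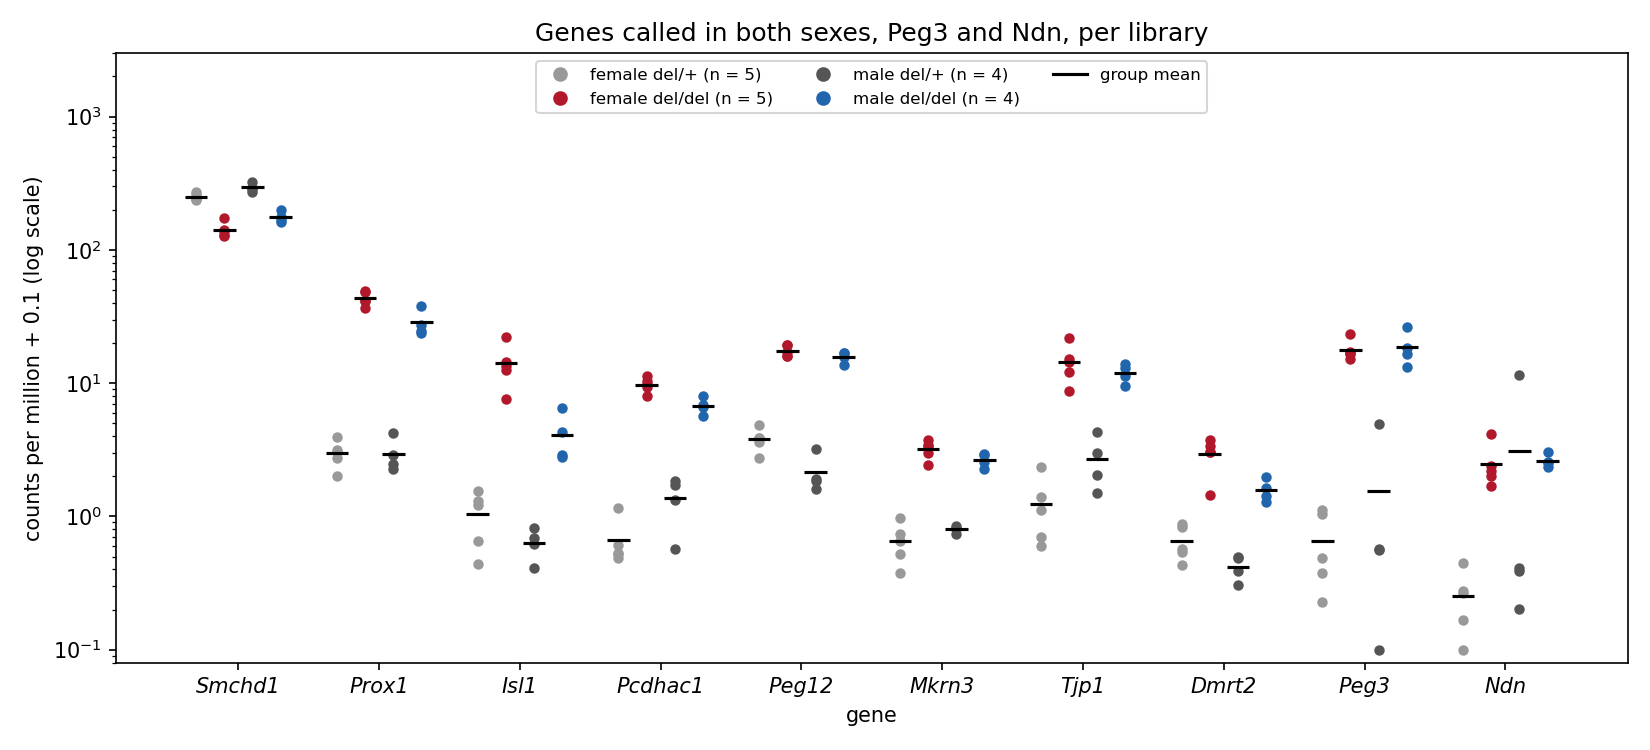
CPM plus 0.1 on a log axis for Smchd1 and 9 further genes, 1 point per library, in female heterozygous (n = 5), female del/del (n = 5), male heterozygous (n = 4) and male del/del (n = 4) libraries, with a bar at the group mean. Prox1 averages 2.87 CPM in female and 2.86 CPM in male heterozygous libraries against 43.1 and 28.4 CPM in female and male del/del libraries, and male heterozygous library 2 stands above the others of its group for Peg3 (4.85 CPM) and Ndn (11.4 CPM).

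X-linked genes other than Xist were slightly higher as a group in female del/del libraries. The median log2 fold change was 0.066 over 429 X-linked genes and -0.0059 over 13068 autosomal genes, a difference of 0.071. Of the X-linked genes 63.6% had a positive log2 fold change, against 48.3% of autosomal genes. They took 3.30 ± 0.0994% of counts in del/del and 3.04 ± 0.0558% in heterozygous libraries (SD, n = 5 each; exact permutation p = 0.00794, two-sided, the smallest the design allows), and every del/del library lay above every heterozygous one in this share. The median of X-linked genes relative to autosomal genes, against the other heterozygous libraries, was -0.0008 in del/del library 2 and -0.0083 in del/del library 5, which is within the range of heterozygous libraries (-0.0604 to 0.0441), and 0.0763 to 0.141 in the other 3. The camera test gave p = 9.74e-05 with the preset correlation and p = 0.0211 with an estimated correlation. The difference remained between 0.048 and 0.089 under every alternative that was run.

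Single X-linked genes mostly did not pass the test. Only 1, 1810030O07Rik (chromosome X, 12654879 to 12673668), a member of the list of genes that escape X inactivation, was called. It rose from 64.7 ± 4.32 to 96.8 ± 8.85 CPM (log2 0.58, SE 0.08, adjusted p = 0.00556), and adjusted over the X-linked genes alone 2 were higher. The odds ratio of X-linked against autosomal genes among calls was 0.921 (95% interval 0.0226 to 5.53, Fisher's exact p = 1); it changed sides of 1 under most alternatives and was 2.53 with DESeq2 (Fisher's exact p = 0.0274) and 3.56 with all 18 libraries (p = 0.00986). Among genes at an unadjusted p under 0.05, 46 X-linked genes were higher and 4 lower, and the odds ratio for the higher ones was 4.05 (95% interval 2.87 to 5.62, Fisher's exact p = 1.99e-13, which takes genes as independent). Xist, the RNA that coats the inactive X chromosome, was at 1145 ± 416 and 1509 ± 347 CPM (log2 0.40, SE 0.24, adjusted p = 0.975), which is within the spread of libraries.

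Of 10 tested escape genes 1 rose and 9 did not pass the test, and adjusted over the list alone also 1 was higher. Ddx3x, an RNA helicase, had a log2 fold change of 0.25 (SE 0.11). The list lay above other genes (median 0.12, camera adjusted p = 0.000101), which was adjusted p = 0.103 with an estimated correlation. None of 25 X-linked immune genes passed the test, and adjusted over the list alone none did either. Cfp, which encodes properdin, had a log2 fold change of 0.50 (SE 0.16) and the RNA sensor Tlr7 of 0.59 (SE 0.28). The list median was 0.17 (camera adjusted p = 0.00562; adjusted p = 0.338 with an estimated correlation). The call was lost with log2 Malat1 CPM as a covariate (median 0.020, adjusted p = 0.733), and del/del library 2 had the lowest mean of the list of all 10 libraries. Malat1 itself was at 1086 ± 306 CPM in female heterozygous and 1481 ± 413 CPM in female del/del libraries (SD, log2 0.45, SE 0.215). A call lost in females with this covariate therefore does not tell RNA quality from genotype. The list exceeded every heterozygous library in del/del libraries 1, 3 and 5 only, as did plasmacytoid dendritic cell genes.

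**Figure D2:**
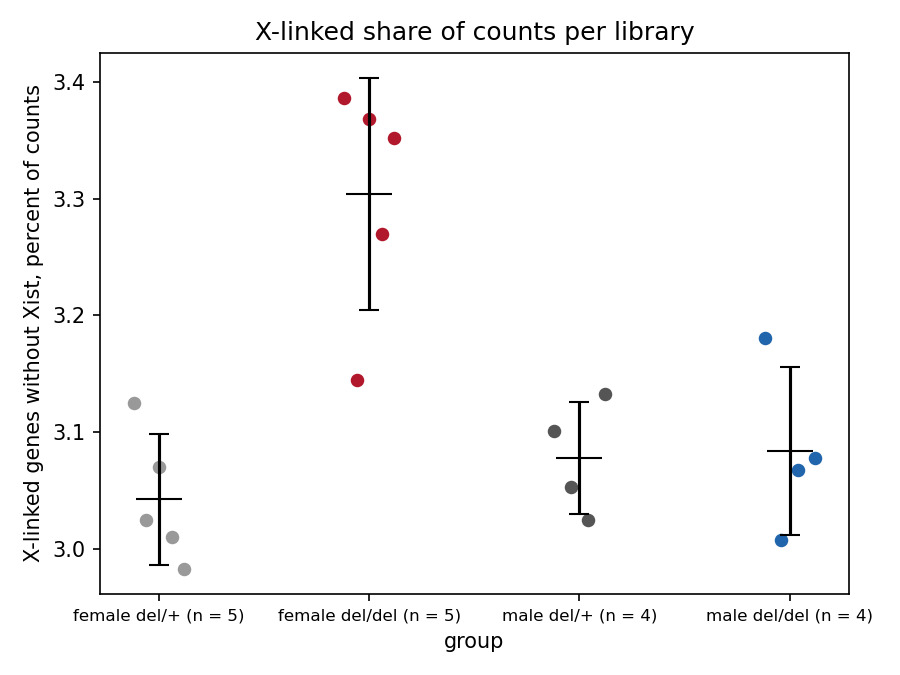
Percent of counts from X-linked genes other than Xist in each library, by group, on an axis that does not start at 0; points are libraries, horizontal bars the mean and error bars 1 SD. The female del/del libraries average 3.30% and the female heterozygous libraries 3.04%, while the male groups average 3.08% each.

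Lists of immune response and B cell state genes shifted in most but not all female del/del libraries, by small amounts. The interferon-stimulated list was higher, with 33 of 35 tested members positive and a median of 0.22 (camera adjusted p = 2.40e-09). It was adjusted p = 0.232 with an estimated correlation. In it only Ifi27l2a passed the test over all genes (47.3 ± 6.28 to 73.8 ± 9.17 CPM, log2 0.64, SE 0.11, adjusted p = 0.0301), and adjusted over the list alone 3 were higher; Oas2 was at log2 0.81 (SE 0.21; called with DESeq2, adjusted p = 0.0414) and Isg15 at 0.70 (SE 0.20). The Ifi27l2a call was lost without heterozygous library 1, 3, 4 or 5 or del/del library 1, 2 or 4. The age-associated B cell list had 20 of 20 members positive and a median of 0.35 (camera adjusted p = 1.92e-07; adjusted p = 0.170 with an estimated correlation). Its members Zbtb32, a B cell repressor, and the costimulatory gene Cd80 had log2 fold changes of 1.18 (SE 0.39) and 1.40 (SE 0.51), and none passed the test over all genes or adjusted over the list alone. For both lists del/del library 2 had the lowest mean log2 CPM of all 10 libraries (4.04 for interferon and 3.61 for age-associated genes), while the other 4 del/del libraries lay above every heterozygous one. With log2 Malat1 CPM as a covariate the age-associated call was lost (median 0.12, adjusted p = 0.0551).

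All 10 tested Hox genes were positive in females, with a median of 0.41 (camera adjusted p = 0.000832; adjusted p = 0.170 with an estimated correlation). Hoxc4 was at log2 2.28 (SE 0.74) and Hoxa9 at 0.48 (SE 0.21), and none passed the test. The germinal centre and activation list (19 of 21 positive, median 0.17, adjusted p = 0.0130) contained Rgs13 at 0.74 (SE 0.29); this was adjusted p = 0.170 with an estimated correlation, and the call was lost without del/del library 5. The p53 target list (12 of 18 positive, median 0.13, adjusted p = 0.00653) contained the apoptosis gene Bbc3 at 0.55 (SE 0.20). It also contained Cdkn2a at 1.24 (SE 0.38), which acts upstream of p53 and is not itself a target. The p53 target list was at adjusted p = 0.0776 with an estimated correlation and 0.0174 with fry. Its mean log2 CPM was 4.523 to 4.74 in del/del libraries, above every heterozygous library (4.335 to 4.484). The mature B cell list (23 of 24 positive, median 0.16, adjusted p = 0.0266) contained Ltb at 0.37 (SE 0.20), at adjusted p = 0.578 with an estimated correlation, and its call was lost without heterozygous library 1, 2 or 5 or del/del library 1, 3 or 5, with a median of -0.060 without the last. With log2 Malat1 CPM as a covariate the mature B cell list was called lower (median -0.13, adjusted p = 0.0482), and the Hox (median 0.14, adjusted p = 0.242) and germinal centre (median 0.050, adjusted p = 0.508) calls were lost. Del/del library 2 lay below every heterozygous library for the mature B cell and germinal centre lists, and the mature B cell and Hox lists exceeded every heterozygous library in del/del libraries 1, 3 and 5 only, as did plasmacytoid dendritic cell genes. In these 4 lists no member passed the test over all genes.

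Cell cycle genes had 34 of 34 negative values in the female comparison, with a median of -0.22 (camera adjusted p = 3.59e-10; adjusted p = 0.338 with an estimated correlation), but the libraries differed. The mean log2 CPM was below every heterozygous library (7.10 to 7.44) in del/del libraries 1, 3 and 5 and above every one in del/del libraries 2 (7.502) and 4 (7.483). Plasmacytoid dendritic cell genes were above every heterozygous library (5.68 to 6.42) in the first 3 (6.66, 6.85 and 6.88) and within that range in the other 2 (5.93 and 5.74). With log2 Malat1 CPM as a covariate the call was lost (median -0.014, adjusted p = 0.733). Aurkb and Ccnb1 were at -0.26 (SE 0.15) and -0.30 (SE 0.17). The pro-B and pre-B list (median -0.093, adjusted p = 0.0485) held Lef1 at -0.33 (SE 0.19), and was at adjusted p = 0.404 with an estimated correlation; its call was lost without heterozygous library 2, 3 or 5 or del/del library 3 or 5, with autosomal TMM factors (adjusted p = 0.0503) and with all 18 libraries (0.0587), and its median was 0.058 with Malat1 as a covariate; del/del libraries 3 and 5 lay below every heterozygous library and del/del library 4 above. Silencing factors (median -0.091, adjusted p = 0.00590) held Dnmt3b at -0.34 (SE 0.15), and were at adjusted p = 0.345 with an estimated correlation, and the call was lost without del/del library 5 and with Malat1 as a covariate (adjusted p = 0.451). They lay below every heterozygous library in del/del libraries 1, 3 and 5 and above in del/del library 4. The B identity list (median 0.0081) and the plasma cell list (median 0.084, adjusted p = 0.121) were not called.

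Markers of other cell types differed in part of the female del/del libraries. Plasmacytoid dendritic cell genes, a B220+ type that the sort does not exclude, had 19 of 20 members positive and a median of 0.43 (camera adjusted p = 4.73e-07). The list was at adjusted p = 0.250 with an estimated correlation, and its call was lost with Malat1 as a covariate (median 0.040, adjusted p = 0.285). Its mean log2 CPM exceeded every heterozygous library in del/del libraries 1, 3 and 5, while del/del libraries 2 (5.93) and 4 (5.74) lay within the heterozygous range. Klk1 was at log2 1.20 (SE 0.42) and Il3ra at 0.51 (SE 0.12); none passed over all genes with edgeR, although DESeq2 called Il3ra (adjusted p = 0.0183), and 1 was higher adjusted over the list alone. Erythroid genes had 1 of 19 positive and a median of -0.67 (camera adjusted p = 3.48e-14; adjusted p = 0.103 with an estimated correlation). Slc4a1 was at -0.81 (SE 0.23) and Hbb-b1 at -1.51 (SE 0.48), none passed over all genes, and 5 were lower adjusted over the list alone; del/del libraries 2 and 5 lay below every heterozygous library. T and NK cell genes had a median of -0.19 (adjusted p = 0.0130, direction lower) with Klrb1c at -0.41 (SE 0.21); this was adjusted p = 0.502 with an estimated correlation, and the call was lost without heterozygous library 2 or 4 or del/del library 2 or 4 and with voom, where the direction turned higher (adjusted p = 0.901). Myeloid genes (median 0.16, mean 0.090, camera direction lower, adjusted p = 0.696), stem and progenitor genes (adjusted p = 0.415) and stroma and megakaryocyte genes (adjusted p = 0.326) were not called. In all, 17 of 22 lists were called with the preset correlation and 3 with an estimated correlation, the clustered protocadherins, the imprinted list and the Snrpn cluster. Every member of the Snrpn cluster list is also in the imprinted list, so the imprinted and Snrpn cluster calls share genes.

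**Figure D3:**
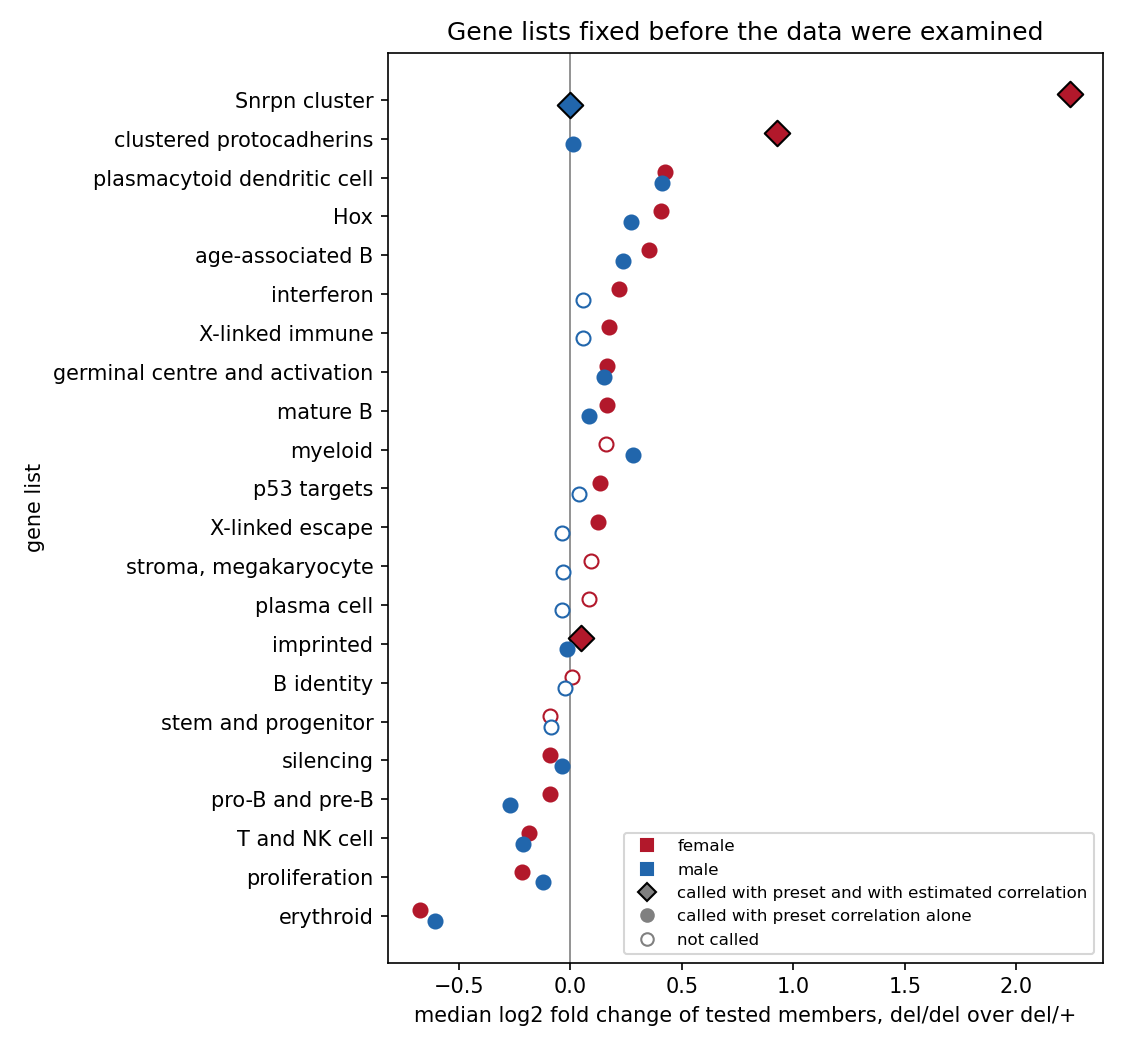
Median log2 fold change (del/del over heterozygous, horizontal axis) of the tested members of 22 gene lists (vertical axis) in females (red) and males (blue); diamonds are lists called with the preset and with an estimated correlation, filled circles those called with the preset correlation alone, open circles those not called. The Snrpn cluster is at 2.24 and the clustered protocadherins at 0.93 in females, and the erythroid list is at -0.67 in females and -0.61 in males.

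In male B cells, 16 of 13413 genes were called, 15 higher and 1, Smchd1, lower. Prox1 rose from 2.86 ± 0.870 to 28.4 ± 6.58 CPM (log2 3.27, SE 0.23, adjusted p = 0.000577, n = 4 and 4). Peg12 rose from 2.04 ± 0.726 to 15.7 ± 1.497 CPM (log2 2.91, SE 0.21, adjusted p = 0.000577) and Vstm2b from 0.667 ± 0.202 to 8.02 ± 1.98 CPM (log2 3.58, SE 0.27, adjusted p = 0.000577). Nr3c2, the mineralocorticoid receptor, rose from 13.004 ± 1.20 to 31.4 ± 4.46 CPM (log2 1.27, SE 0.12, adjusted p = 0.00281). Xkr6 (log2 2.43, SE 0.28, adjusted p = 0.0110), Isl1 (log2 2.90, SE 0.37, adjusted p = 0.0179) and Arhgef12 (log2 0.53, SE 0.07, adjusted p = 0.0179), rose as well.

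In males 448 genes had an unadjusted p under 0.05, 311 higher and 137 lower. The authors' deposited table for males held 16 genes at an adjusted p under 0.05, the same 16. The count was 49 with DESeq2 and 5 with the plasmacytoid dendritic cell score as a covariate, namely Prox1, Peg12, Vstm2b, Nr3c2 and the unnamed model Gm16028. The 11 lost calls kept their sign, with a median ratio of the log2 fold change to that without the covariate of 0.954 and of the SE of 1.28, as for Xkr6 at 2.45 (SE 0.36) and Tjp1 at 2.17 (SE 0.37). The count was 5 without heterozygous library 1 or del/del library 3, 6 without del/del library 1, 9 without heterozygous library 4, 10 without del/del library 4 and 22 without heterozygous library 2. Prox1, Peg12, Vstm2b and Nr3c2 passed in each of these 8 fits. The call of Xkr6 was lost without heterozygous library 1 or 4 or del/del library 3, that of Mkrn3 without heterozygous library 1 or 4 or del/del library 1 or 3, and that of Isl1 also without heterozygous library 3. Arhgef12 passed only without heterozygous library 2 or del/del library 2, Pcdhac1 only without heterozygous library 2 or 4, Tjp1 only without heterozygous library 2 or 3, and Dmrt2 in none. With all 18 libraries in one fit the calls of Vstm2b (adjusted p = 0.389), Nr3c2 (0.0904), Xkr6 (0.916) and Arhgef12 (0.312) were lost, as were those of Isl1 with voom (0.0725), of Dmrt2 without a filter (0.0736) and of Xkr6, Isl1, Arhgef12 and Dmrt2 after thinning (0.0519 to 0.118). With each del/del library paired with the heterozygous library of the nearest animal number, 13 genes were called, 9 of them among the 16, and Mkrn3 (log2 1.86, SE 0.23), Xkr6 (2.46, SE 0.30), Tjp1 (2.23, SE 0.27) and Dmrt2 (2.16, SE 0.31) were not (adjusted p = 0.0608 to 0.119).

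Of 39 tested imprinted genes in males, 2 rose, Peg12 and Mkrn3 (log2 1.86, SE 0.22, adjusted p = 0.0110), and 37 did not pass the test; adjusted over the list alone, 3 were higher. Peg3 had a log2 fold change of 3.46 (SE 0.70, adjusted p = 0.227) and Ndn of -0.35 (SE 1.01, adjusted p = 0.9998). Without heterozygous library 2 Peg3 was at 5.70 (SE 0.45, adjusted p = 0.00114) and Ndn at 3.30 (SE 0.34, adjusted p = 0.00655). Peg3 was also called with that library kept, with all 18 libraries in one fit (log2 3.48, adjusted p = 0.0232), with Malat1 as a covariate (4.57, adjusted p = 0.0429) and with the erythroid score as a covariate (5.20, adjusted p = 0.0122). The imprinted list was called higher by camera (adjusted p = 0.00836) although its median was -0.016 and its mean 0.10; this was adjusted p = 0.171 with an estimated correlation, and the call was lost without heterozygous library 4, without a filter (adjusted p = 0.201) and with voom (0.123). The Snrpn cluster, with 2 of 5 members higher and a median of -0.0023 but a mean of 0.84, was called higher (adjusted p = 8.48e-16; adjusted p = 0.00312 with an estimated correlation). Of 6 protocadherin rows 1 rose, the alpha cluster row Pcdhac1 (log2 2.39, SE 0.31, adjusted p = 0.0179), and adjusted over the list alone 2 were higher. The protocadherin list (median 0.013, mean 0.61, adjusted p = 0.00202) was at adjusted p = 0.256 with an estimated correlation and 0.231 with voom, and Pcdhb5 was at log2 2.41 (SE 0.46, adjusted p = 0.183; 0.0335 with DESeq2).

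X-linked genes did not shift in male libraries by more than the spread. The median difference from autosomal genes was -0.016 (418 X-linked genes; camera p = 0.382, and p = 0.598 with an estimated correlation), and no X-linked gene was called (odds ratio 0, 95% interval 0 to 8.08, Fisher's exact p = 1). X-linked genes took 3.08 ± 0.0718% of counts in del/del and 3.08 ± 0.0483% in heterozygous libraries (SD, n = 4 each; exact permutation p = 0.914, two-sided; the smallest possible is 0.0286). Without del/del library 1 the median difference was -0.030 and was called lower by camera. The escape list (median -0.036, adjusted p = 0.418), the X-linked immune list (median 0.057, adjusted p = 0.166; Tlr7 at 0.47, SE 0.13) and the Y-linked list (median -0.011, mean 0.0055, adjusted p = 0.975) were not called.

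Precursor B cell genes were lower in part of the male del/del libraries, with 2 of 22 pro-B and pre-B members positive in the comparison and a median of -0.27 (camera adjusted p = 1.91e-11; adjusted p = 0.254 with an estimated correlation). Del/del libraries 3 (6.60) and 4 (6.67) lay below every heterozygous library, while del/del libraries 1 (7.05) and 2 (6.92) lay within the heterozygous range (6.89 to 7.22). The recombinase gene Rag1 was at -0.60 (SE 0.19) and Dntt, the terminal transferase, at -0.43 (SE 0.15), while Flt3, a cytokine receptor of early progenitors, was at 0.48 (SE 0.14), and none passed the test over all genes or adjusted over the list alone. The age-associated list was higher (15 of 20 positive, median 0.24, adjusted p = 0.00202), with Apoe at 0.64 (SE 0.21), and was at adjusted p = 0.483 with an estimated correlation; its call was lost without heterozygous library 3 or del/del library 1, and del/del library 2 (3.95) lay below every heterozygous library. The germinal centre and activation list (median 0.15, adjusted p = 0.0152, Cd69 at 0.46, SE 0.13) was at adjusted p = 0.537 with an estimated correlation and lost its call without heterozygous library 2 or 3 or del/del library 1 or 3, with voom (adjusted p = 0.0693), with pairs of nearest animal numbers (0.0625) and with Malat1 as a covariate (0.0929). The mature B cell list (median 0.085, adjusted p = 0.0204, Fcrl1 at 0.17, SE 0.09) was also at adjusted p = 0.537 with an estimated correlation, passed with a library left out only without heterozygous library 4 or del/del library 2, and was not called with all 18 libraries (0.118) or with Malat1 (0.0929). Hox genes (7 of 7 positive, median 0.27, adjusted p = 0.00831, Hoxa7 at 0.43, SE 0.19) were at adjusted p = 0.331 with an estimated correlation and lost their call without del/del library 3.

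The proliferation list was lower in males (median -0.12, adjusted p = 3.70e-06, Kif11 at -0.31, SE 0.15; adjusted p = 0.537 with an estimated correlation), as were silencing factors (median -0.038, adjusted p = 0.0400, Ezh2 at -0.23, SE 0.14; adjusted p = 0.537 with an estimated correlation). The first call was lost without heterozygous library 2, and the second without heterozygous library 1, 2 or 3 or del/del library 3 or 4, with other filters, with all 18 libraries and with Malat1 (adjusted p = 0.0510 to 0.0596). Both lists lay below every heterozygous library in del/del libraries 3 and 4 only. The B identity (adjusted p = 0.0540), plasma cell (0.148), interferon (0.461) and p53 target (0.161) lists were not called. No member of these lists passed the test over all genes.

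Markers of other cell types differed in part of the male libraries too. Plasmacytoid dendritic cell genes had 18 of 20 positive and a median of 0.41 (camera adjusted p = 6.22e-11; adjusted p = 0.256 with an estimated correlation), with Il3ra at 0.61 (SE 0.12), Pacsin1 at 0.53 (SE 0.11) and Klk1 at 0.85 (SE 0.27). DESeq2 called Il3ra (adjusted p = 0.00503) and Pacsin1 (0.00883), Klk1 was called by edgeR without del/del library 4 (1.08, adjusted p = 0.0210), and 2 were higher adjusted over the list alone. Their mean log2 CPM exceeded every heterozygous library in del/del libraries 1, 2 and 3, and del/del library 4 (4.94) lay below every one. Erythroid genes had a median of -0.61 (adjusted p = 3.23e-06; adjusted p = 0.487 with an estimated correlation), with Klf1 at -1.66 (SE 0.71) and Slc4a1 at -0.66 (SE 0.31). Every del/del library lay within the heterozygous range, and without heterozygous library 2 the median was -0.18 and the adjusted p 0.186. T and NK cell genes were lower (median -0.21, adjusted p = 0.00523, Gzma at -0.71, SE 0.27; adjusted p = 0.537 with an estimated correlation), a call that was lost with voom (adjusted p = 0.148), without del/del library 3 and without heterozygous library 4, where the median was -0.011. Myeloid genes were higher (30 of 30 positive, median 0.28, adjusted p = 0.00275, Csf1r at 0.29, SE 0.16; adjusted p = 0.556 with an estimated correlation), and the call was lost with voom (median 0.039, adjusted p = 0.209), with pairs of nearest animal numbers (median 0.139, adjusted p = 0.0625) and without heterozygous library 3 and turned to lower without del/del library 3, at a median of -0.13. Stem and progenitor genes (adjusted p = 0.682; 1 member, Ly6a, higher adjusted over the list alone and chosen after its value was seen) and stroma and megakaryocyte genes (adjusted p = 0.369) were not called. In all, 14 of 23 lists were called with the preset correlation and 1, the Snrpn cluster, with an estimated correlation; without heterozygous library 3 the first number was 9.

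Genes changed in females and in males overlapped far beyond independent lists. Among 13175 genes tested in both sexes, 31 were called in females and 12 in males, and 8 in both: Prox1, Mkrn3, Peg12, Tjp1, Isl1, Pcdhac1, Dmrt2 and Smchd1. Independent lists would share 0.0282 genes (odds ratio 1145, 95% interval 276 to 8192, Fisher's exact p = 1.73e-19), and the female and male fits shared no library. The first 7 rose in both sexes, with Tjp1 at 3.73 (SE 0.37) and 2.15 (SE 0.29, adjusted p = 0.0226) and Dmrt2, a transcription factor of the DM domain family, at 2.37 (SE 0.34, adjusted p = 0.00676) and 2.14 (SE 0.30, adjusted p = 0.0271). Of the 31 female calls 26 had the same sign in males, and 12 of 12 male calls had the same sign in females. Across genes, which are not independent replicates, the log2 fold changes had a Spearman correlation of 0.355. The shared number was 24 with DESeq2 and 3 at an adjusted p under 0.01. With pairs of nearest animal numbers it was 5, without Mkrn3, Tjp1 and Dmrt2, whose male calls were lost there, and it was 2 with the plasmacytoid dendritic cell score as a covariate. It was also 2 without male heterozygous library 1 or male del/del library 1 or 3, 4 without male heterozygous library 4, 5 without male heterozygous library 3 or male del/del library 2 or 4, and 14 without male heterozygous library 2.

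**Figure D4:**
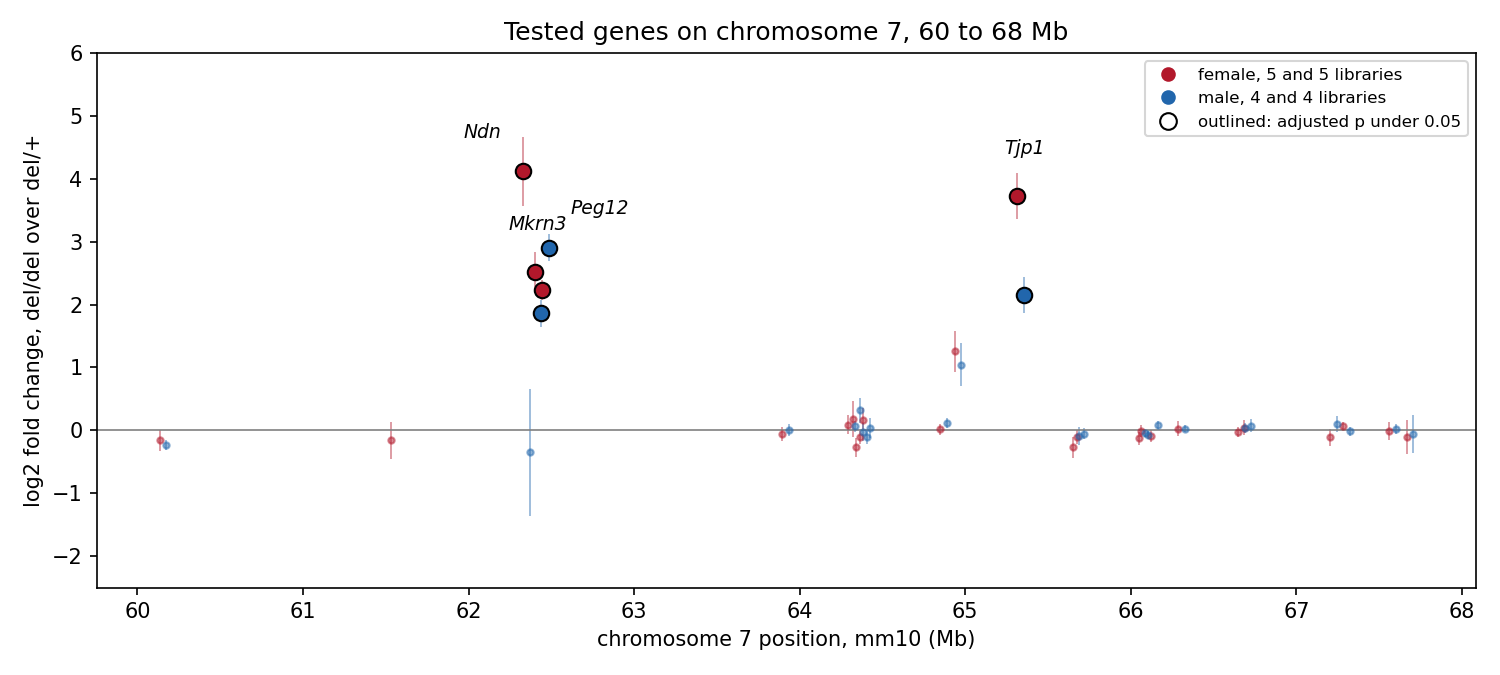
Log2 fold change (del/del over heterozygous, vertical axis) with SE bars of each gene tested on chromosome 7 between 60 and 68 Mb (horizontal axis, mm10, with the sexes drawn slightly apart), in females (red, 5 and 5 libraries) and males (blue, 4 and 4 libraries), with called genes outlined. Ndn, Mkrn3, Peg12 and Tjp1 are called in females and the last 3 also in males, while most neighbours lie near 0. The stretch was chosen because it holds these called genes.

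The effect of deletion was also compared directly between the sexes. Over 14017 genes, the edgeR interaction test called 0, with 150 genes higher and 53 lower in the female effect at an unadjusted p under 0.05, while voom called 0 and DESeq2 called 4. Those 4, chosen after their values were seen, were Id4, 1810030O07Rik, Xlr and the unnamed model AC214054.1, of which 1810030O07Rik and Xlr are X-linked. For Xlr (DESeq2 -7.87, SE 1.78) and AC214054.1 (-3.80, SE 0.67) the difference was negative, so the female effect lay below the male one. Id4, at 23.2 (SE 2.34) with DESeq2, had 0 reads in female heterozygous libraries, so the size of its difference is not fixed by the counts. The edgeR adjusted p was 0.99994 for both Id4 and Xlr. For 1810030O07Rik the DESeq2 difference was 0.60 on the log2 scale (SE 0.13, adjusted p = 0.0138), and the edgeR adjusted p was 0.479. X-linked genes as a group differed: the female effect exceeded the male effect by a median of 0.077 over 443 X-linked genes, 0.067 above autosomal genes (camera p = 7.86e-06, and p = 0.00805 with an estimated correlation). Of 23 lists, 11 were called for a difference with the preset correlation, 8 with the larger value in females, and 2 with an estimated correlation. These 2 were the escape list (median 0.20, adjusted p = 2.07e-07; adjusted p = 0.00850 with an estimated correlation) and the clustered protocadherins (median 0.87, adjusted p = 2.64e-07; adjusted p = 0.00850 with an estimated correlation). Xist, near the floor in males, raised the mean of the escape list to 0.43. Without Xist, left out after its value was seen, the list had a median of 0.19 and a mean of 0.18, with 8 of 9 members positive (adjusted p = 4.85e-06; adjusted p = 0.0314 with an estimated correlation). With 0 genes called, an X-linked share of interaction calls could not be computed.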

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

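Of the tests in this part, the covariates, the thinning, the splits by pairs and the sharing of the genes of smallest p were chosen after the data were seen, while the splits of the libraries and the fits that left out a library were not. In 11 of 150 groups of values a library stood apart from the rest of its group, where chance gives about 1 in 20 groups. Male heterozygous library 2 stood apart for Peg3 (4.85 CPM, the others 0 to 0.469), Ndn (11.4 CPM, the others 0.103 to 0.313) and the erythroid transcription factor Klf1 (14.98 CPM, the others 1.22 to 2.74). The same library held 51 Xist counts, against 2 to 7 in the other male libraries. Smchd1 was at 173.5 CPM in female del/del library 4 (the others 128 to 140). Other values that stood apart were Pcdhac1 at 1.05 CPM in female heterozygous library 3, Hoxc4 at 0.593 CPM in female heterozygous library 1, Peg3 at 23.4 CPM in female del/del library 5, Pcdhb5 at 2.62 CPM in female del/del library 2, Ndn at 4.03 CPM in female del/del library 1, Pcdhb5 at 0.411 CPM in male heterozygous library 1 and Hoxa7 at 6.80 CPM in male heterozygous library 4.

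The effect of deletion differed between the sexes, by the interaction of sex and genotype with camera's preset correlation, for 11 lists and for X-linked genes. The median difference, female minus male, was 0.20 for escape genes, 0.096 for X-linked immune genes, 0.87 for clustered protocadherins, 0.14 for pro-B and pre-B genes, 0.089 for B identity genes, 0.145 for plasma cell genes, 0.25 for age-associated B cell genes, 0.17 for interferon genes, -0.079 for proliferation genes, -0.072 for myeloid genes, -0.095 for erythroid genes and 0.077 for X-linked genes. With an estimated correlation the escape genes, the clustered protocadherins and the X-linked genes passed and the other 9 lists did not. Heterozygous libraries of the sexes differed in cell type markers and were deposited apart, so these differences cannot be assigned to sex alone.

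Other splits of the libraries were used to ask whether chance can be excluded. In females 34 genes were called, and 3 of 100 splits called as many, the real one included, a share under 0.05 over these 100 splits. The highest other split called 1761 genes and set heterozygous libraries 1 and 3 with del/del libraries 1, 3 and 5 against the rest, and a further split called 92; a split with many times the real count points to a structure of the samples. Of these splits 1 of 100 called as many lists (17, the highest other 15). Among the splits drawn, 13 part all 5 female pairs of nearest animal numbers, the real one included. The other 12 of them called 0 genes and at most 15 lists, but 13 splits are too few for a share under 0.05. In males 2 of 35 splits called as many genes (16, with more than 200 in the highest other) and 2 of 35 as many lists (14, the highest other 14), so chance is not excluded for either count over all splits. All 4 male pairs of nearest animal numbers had correlated deviations (0.105 to 0.33), and the split with more than 200 calls set the pairs of del/del libraries 1 and 3 against the other 2. Of the 8 splits that part all 4 pairs, the real one included, the other 7 called 0 genes and at most 12 lists, but 8 splits are too few for a share under 0.05. For the X-linked difference in males, 22 of 35 splits were as large (-0.016, the highest other 0.053 in size). With 0 interaction genes called, all 100 regroupings had to reach that number (the highest other 132), so they decide nothing. Sharing of calls between the sexes reached 8 in 1 of 100 regroupings, the real one, and 0 in the others, which decides nothing either, because 93 of 99 other female and 32 of 34 other male splits called 0 genes. The 31 female and 12 male genes of smallest p, among genes tested in both sexes, shared 8. Of 100 regroupings 1, the real one, shared as many (the highest other 1), a share under 0.05 over regroupings drawn without regard to the pairs.

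X-linked genes were higher as a group in female del/del libraries, by a median difference of 0.0714. Of 100 splits 4 gave a difference as large, the real one included and the highest other 0.0872, a share under 0.05 over these 100 splits. Among the 13 splits drawn that part all 5 female pairs of nearest animal numbers, the highest other reached 0.059 in size. Those 13 splits, the real one included, are too few for a share under 0.05, so chance is not excluded among them. Removing the trend on gene length and GC content left 0.0663, against an upper limit of 0.0154 over 10000 random autosomal sets, so that trend does not account for all of it. With log2 Malat1 CPM as a covariate 0.0480 was left. Malat1 is a single gene and was at 1086 ± 306 CPM in heterozygous and 1481 ± 413 CPM in del/del libraries (SD). This covariate therefore cannot decide how much of the difference goes with RNA quality. A biological effect of the genotype on the X chromosome, a question set before the data were examined, remains a hypothesis. Cell composition stays open in part, since the difference was 0.0497 with the plasmacytoid dendritic cell score and 0.0543 with the erythroid score as covariate.

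Plasmacytoid dendritic cell genes were higher and erythroid genes lower by group in both sexes, although the first did not exceed the heterozygous range in female del/del libraries 2 and 4 and male del/del library 4. Genes largely private to plasmacytoid dendritic cells lay above the list members that B cells also express, by 0.0821 in females and 0.283 in males, which is consistent with a larger share of these B220+ cells, although 0.0821 is smaller than the spread of the 8 private genes in females (0.191 to 1.20). All 4 haemoglobin genes were negative in both sexes, and their level followed Alas2 over libraries (Spearman 0.903 in females and 0.905 in males), which is consistent with fewer erythroid cells or less of their RNA. Hbb-b1 was at 107 ± 89.4 CPM in female heterozygous and 37.5 ± 12.6 CPM in female del/del libraries (SD), and a B220 gate would remove erythroid cells. Only heterozygous libraries 2 (157.4 CPM) and 4 (240.5 CPM) lay above the del/del range of 25.85 to 58.91 CPM. The other heterozygous libraries, at 32.5 to 53.99 CPM, lay within it. A change of marrow composition by genotype stays open as a biological explanation, and the male erythroid call was lost without heterozygous library 2.

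More genes were called in females (34) than in males (16). Female subsets of 4 and 4 libraries thinned to the male depths called between 13 and 42 genes with a median of 19, and 9 of 25 called no more than the males, so the gap is within what fewer and shallower libraries gave in females. Simulated counts with the male spread and library sizes recovered more of the 1.5-fold (58.0%) and 2-fold changes (84.0%) than the female ones (44.9% and 74.0%). They recovered fewer of the 4-fold changes (93.9% against 97.8%). Tested genes had a median of 30.2 CPM in female and 29.5 CPM in male heterozygous libraries, but genes called higher had 0.554 and 0.731 CPM. The simulation, which drew changed genes at random, therefore does not decide the question. By the thinned subsets, the number and depth of libraries stay open as a cause. Without male heterozygous library 2 the males called 22 genes, 14 of them also called in females. The interaction test called 0 genes with edgeR (150 higher and 53 lower at an unadjusted p under 0.05; voom 0, DESeq2 4), so a difference by sex in single genes was not shown and stays open.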

How the results depend on the processing

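Alternatives for the Malat1, plasmacytoid dendritic cell and erythroid covariates, thinning, Xist left out of the escape list and pairs of nearest animal numbers were chosen after seeing the data; the cause was not tested unless named. Female Smchd1 kept its direction and call under every alternative run, and the female X-linked difference also did, at 0.048 to 0.089. Female calls numbered 56 with voom, 92 with DESeq2, 58 with all 18 libraries in one fit, 13 with the erythroid covariate, and 26 to 41 with a library left out. Male calls numbered 49 with DESeq2, 6 at an adjusted p under 0.01, 10 after thinning, 5 with the plasmacytoid dendritic cell covariate, and 5 to 22 with a library left out. DESeq2 called 4 interaction genes. Lists called numbered 3 (estimated correlation), 4 (fry) and 10 (Malat1) in females and 1 (estimated correlation) and 1 (fry) in males, with 9 to 15 in males with a library left out. The female X-linked odds ratio, below 1 at first, was 2.95 without a filter, 1.11 with the stricter filter, 1.73 with voom, 2.53 with DESeq2, 3.56 with all 18 libraries, 1.22 at an adjusted p under 0.01, 1.33 after thinning, 1.97 with Malat1, 1.38 with pairs, and 0.956 to 3.29 with a library left out. Male Smchd1 was between -0.80 and -0.69 with a library left out and lost its call without heterozygous library 1 (-0.75), del/del library 1 (-0.70) or del/del library 3 (-0.72), where fewer libraries were tested, and with the plasmacytoid dendritic cell covariate (-0.62). The male X-linked difference was -0.030 to -2.957e-05 with a library left out and passed without del/del library 1 (-0.030). Reversed were the female T and NK list with voom (-0.064, the test turning higher), pro-B and pre-B genes (0.058), mature B cell genes (-0.13) and Xist (-0.011) with Malat1, Xist (-0.0078), Hbb-b1 (0.098) and Lef1 (0.14) with the erythroid covariate, mature B cell genes without female del/del library 5 (-0.060, up to 0.315 with others left out), male T and NK genes without heterozygous library 4 (-0.011, down to -0.396), male myeloid genes without del/del library 3 (-0.13, up to 0.436), and male Ndn with voom (2.07), Malat1 (2.12), pairs (1.27), the erythroid covariate (2.73) and over libraries left out (-0.74 to 3.30). The pairs gave 23 female calls, all among the 34, and 13 male calls, 9 of them among the 16, and the male myeloid (0.139, adjusted p = 0.0625) and germinal centre (0.132, adjusted p = 0.0625) lists were not called with them. No share of X-linked interaction calls could be computed. Depth limits genes near 1 CPM, where 1 count was worth 0.034 to 0.102 CPM.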

Other observations

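The run of neighbouring X-linked genes was tested only after the pattern was seen, the test of neighbouring animal numbers was chosen after the splits of the libraries were seen, and the genes named here were chosen after their values were seen. Further genes were called in females. Jag1, a Notch ligand, rose by a log2 fold change of 3.05 (SE 0.34, adjusted p = 0.00119), Fzd10, a Wnt receptor, by 3.97 (SE 0.51, adjusted p = 0.00292), Lhx2, a LIM homeobox factor, by 2.04 (SE 0.31, adjusted p = 0.01001) and Gad1, which makes the transmitter GABA, by 1.06 (SE 0.18, adjusted p = 0.0309), with n = 5 and 5, and of these 4 only Jag1 was called with the erythroid score as a covariate or with pairs of nearest animal numbers, where Fzd10 was at 4.04 (SE 0.60, adjusted p = 0.0581), Lhx2 at 1.99 (SE 0.33, adjusted p = 0.101) and Gad1 at 1.05 (SE 0.17, adjusted p = 0.0868). In the main male fit, Jag1 (2.50, SE 0.42, adjusted p = 0.0906) and Fzd10 (1.69, SE 0.75, adjusted p = 0.9998) did not pass. Without male heterozygous library 2, Jag1 (3.10, SE 0.40, adjusted p = 0.0195) and Fzd10 (4.25, SE 0.56, adjusted p = 0.0213) passed. With that library kept and the erythroid score as a covariate, Jag1 passed in males as well (3.13, SE 0.33, adjusted p = 0.00928). On chromosome 7 between 60 and 68 Mb, 4 of 26 tested genes were called in females and 3 of 25 in males. This stretch was chosen because it holds called genes, so the counts do not test whether calls cluster there. The other tested members of the Snrpn cluster list are not within it and were not called in either sex. Fam189a1, next to Tjp1 there, was at 1.26 (SE 0.32, adjusted p = 0.291) in females and 1.04 (SE 0.35) in males and did not pass.

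A run of 5 neighbouring X-linked genes, 1810030O07Rik, Med14, Usp9x, Ddx3x and Cask (chromosome X, 12654879 to 13851367), had a mean log2 fold change of 0.54 in females, the highest of any such run of 297 genes (permutation p = 0.0064, one-sided, 10000 shuffles of gene order). A candidate explanation is that neighbouring X-linked genes responded together. In males Cask was at 0.65 (SE 0.19) and the other 4 genes lay between -0.042 and 0.020.

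Xist and Malat1 levels varied together over the 10 female libraries (Pearson 0.926, permutation p = 6e-05; Spearman 0.915, permutation p = 0.00045), the only relation across libraries computed between single genes. Pearson's r was 0.956 without the 2 libraries farthest from the median and 0.904 within genotypes. The log2 ratio of Xist to Malat1 was 0.0397 in del/del and 0.0401 in heterozygous libraries (exact permutation p = 1, n = 5 each).

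Libraries of animals with neighbouring numbers may share an origin, such as a litter or a day of work, which the labels do not state. Deviations from the genotype mean had a mean correlation of 0.162 over 9 pairs of a del/del library and the heterozygous library of the nearest number, against 0.000207 over all reassignments (exact permutation p = 0.000694, one-sided, 2880 reassignments). The correlation was positive in 8 of the 9 pairs and -0.042 for female del/del library 3 and heterozygous library 3.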
